A study of Mus musculus with 12 samples.

How the data were processed

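Total RNA of the proximal jejunum of C57BL/6J mice was sequenced in 12 libraries, 3 in each of 4 groups: room temperature, cold (6 °C), room temperature with antibiotics and cold with antibiotics, each for 30 days. Per the labels' protocols, mice were kept 2 per cage under specific pathogen free conditions and fasted for 5 hours before collection, RNA was extracted with Trizol, and libraries were made from 300 ng of total RNA with the Illumina TruSeq stranded mRNA kit. Per the series design, each library was a pool of 2 mice, so the spread between libraries is that between pools.

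The deposited table gives 1 signal per gene and library, a read count normalized to library size (CPM) made by the authors. Per the submitters' processing notes, TopHat2, HTSeq 0.5.3p9, edgeR 3.4.2 and the mouse genome build mm10 were used, with no role or order stated. The table holds 13055 genes. A filter on low counts appears to have been applied by the authors before deposition and is not given in the sources used here. Checked on the values, each column was made of whole multiples of 1 step, with 100% of values whole within a tolerance of 0.01 reads, and the column sums lay between 932643 and 1.09e+06 CPM. Dividing by the step gave 14152288 to 19099718 reads over the listed genes per library. A count of 3 reads equals 0.152 to 0.229 CPM, a limit that covers counting error alone, and reads are not independent molecules.

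The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Genes with at least 1 CPM in at least 3 of the 12 libraries were tested, 13012 in all, and 43 were removed. Values were taken as log2(CPM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, 8 residual degrees of freedom and eBayes with a trend. Tests were two-sided, and p values were adjusted by Benjamini and Hochberg over the tested genes of each comparison, with a threshold of 0.05 and no fold threshold. The comparisons were cold against room temperature, antibiotics at room temperature, antibiotics in the cold, cold under antibiotics, and the interaction, which is the cold effect with antibiotics minus that without. Log2 changes are given with their SE, CPM levels as mean and SD of 3 libraries, and folds are on the scale of CPM + 1, which understates the fold of genes near 1 CPM. The 4 groups share 1 estimate of the spread.

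Of 41 gene lists, written from general knowledge of the tissue, 39 had at least 5 tested members and were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The same test with an estimated correlation and the rotation test fry were alternatives. Counts of called members are given over all tested genes and adjusted over the list alone.

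Named genes were, for each pairwise comparison, the 10 largest rises and the 10 largest falls among called genes whose 3 libraries of one group all lay above the 3 of the other, without predicted genes, pseudogenes and receptor segments, and the members with the smallest p of each list, up to 4 for a called list and 2 for another. For the interaction they were the called genes, and with fewer than 5 called the 5 with the smallest p. Correlations of log2 changes are across genes, which are not independent replicates, in a family of 3. For the pair of comparisons that share the cold libraries, 100 simulations with unchanged groups gave the correlation that sharing alone produces.

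Alternatives were a pseudocount of 0.25 or 4, no filter, a mean of at least 10 CPM, scaling by the median of ratios, scaling to a common sum, quantile normalization, the 6 compared libraries alone, the replicate number as a block, no variance trend, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, and each library left out in turn. The edgeR test on whole reads called 287, 1749, 2457, 669 and 2 genes in the 5 comparisons in the order given above. The smooth muscle list mean as a covariate, and leaving out room temperature replicate 1 and cold replicate 2 together, were chosen after seeing the data. Other splits of the libraries were counted, 10 for each pairwise comparison and 100 draws for the interaction. In a draw both main effects were fitted, the residuals were reassigned at random among the 12 libraries, and the fitted effects were added back.

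The gene tests were tested on simulated data with 200 changed genes of 13012 in 5 simulations, first run after the deposited values had been analysed. In the comparison of cold against room temperature limma recovered 58.4%, 84%, 94% and 98% of changes of 1.5, 2, 3 and 4-fold, with 8.6 false calls per simulation, and in the interaction 26.8%, 64.4%, 85.2% and 91.6% with 5.6 false calls. In a simulation with independent genes camera called the 1 raised list and 0 others, which leaves the correlation between real genes untested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Positions are on GRCm38, the assembly of mm10. Raw reads were not analysed here.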

Results

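The libraries profiled whole tissue of the proximal jejunum, the part of the small intestine that follows the duodenum, in C57BL/6J mice, an inbred laboratory strain. Mice were housed for 30 days at room temperature or at 6 °C, and at each temperature a group with and a group without a mixture of antibiotics in the drinking water was studied. The antibiotics were given to deplete the whole gut microbiota, and the series asks what part the microbiota plays in the response to cold. Each of the 4 groups held 3 libraries, and each library pooled tissue from 2 mice, so that the 12 libraries stand for separate pairs of animals and n counts pools. A library held 14152288 to 19099718 reads over 13055 genes, and 1 read was worth 0.0507 to 0.0763 normalized CPM, the unit of the deposited table.

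Antibiotic treatment set the libraries apart more than temperature did. The first principal component held 45.1% of the variance, with the 6 untreated libraries between -28.4 and -9.68 and the 6 antibiotic-treated libraries between 13.6 and 23.6. The second component held 16.5%, with the 6 room temperature libraries between 7.11 and 16.0 and the 6 cold libraries between -15.1 and -7.47. Cold replicate 2 stood apart from its group through Rn45s, the ribosomal RNA precursor, which took 10.1% of its reads and 0.0741% to 0.812% of the reads of the other 11 libraries. Lars2, a mitochondrial leucyl-tRNA synthetase gene, was at 12248 CPM in that library against 113 and 115 CPM in the other cold libraries. Within the room temperature group, replicate 1 lay apart in Nos2, the inducible nitric oxide synthase, at 40.6 CPM against 619 and 395 CPM.

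**Figure D1:**
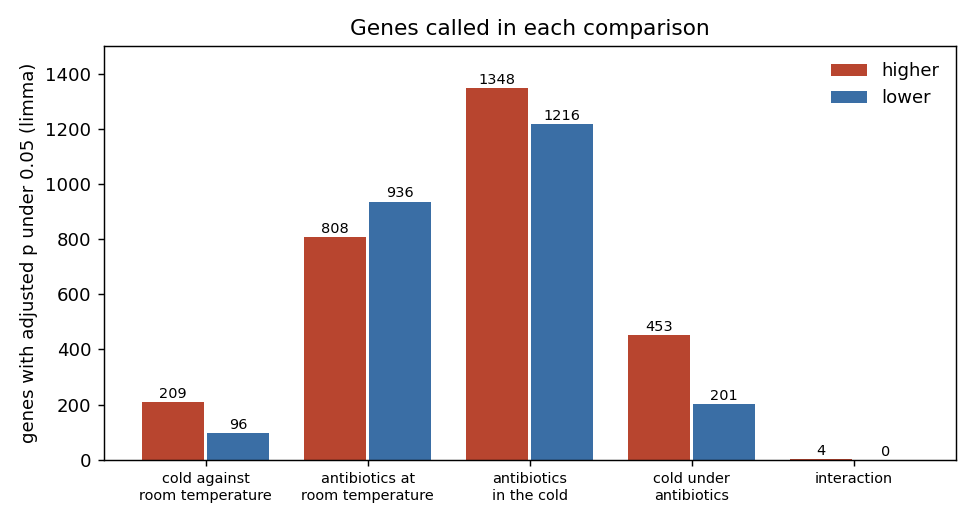
Number of genes with a limma adjusted p under 0.05 in each of the 5 comparisons (bars, starting at 0), higher and lower in the group named first. Antibiotics in the cold gave 1348 higher and 1216 lower genes, and the interaction of cold and antibiotics gave 4 higher and 0 lower.

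Cold without antibiotics raised Fkbp5, Pck1, Pdk4, Zbtb16 and Angptl4 the most among the named genes. Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527 of GRCm38), rose 9.03-fold, from 39.1 ± 24.6 to 299 ± 52.8 CPM (mean ± SD, n = 3), a log2 change of 3.18 ± 0.47 (SE, limma adjusted p = 0.00483). Pdk4, the kinase that turns off pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), rose 5.62-fold from 32.3 ± 29.7 to 147 ± 35.2 CPM, with a log2 change of 2.49 ± 0.42. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 5.27-fold (2.40 ± 0.40), and Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, rose 5.92-fold (2.57 ± 0.59). The other named rises were Zbtb16, Fam134b, Eif4ebp3, Fam43a, the cytochrome P450 gene Cyp3a44 and Fut4, with log2 changes from 1.52 to 2.47. The falls were smaller, led by the glycosyltransferase gene B3galt5 (-1.35 ± 0.26) and by Ciita, the transactivator of MHC class II genes (-1.32 ± 0.24), then Exph5, Fras1, Lipg, Olfr165, the carboxylesterase genes Ces2a and Ces2b, Tifa and Apol10a, between -0.95 and -1.23. In all, 305 of 13012 tested genes passed the limma test, 209 higher and 96 lower, and 43 of them differed by over 2-fold.

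By list, the metabolic groups of this comparison held few called members, and camera called 13 of 39 lists where another split of the same 6 libraries called 25. Of 42 nuclear genes of oxidative phosphorylation, 5 rose and 0 fell (10 rose when adjusted over the list alone), among them Cox5b (0.43 ± 0.10) and Ndufa4 (0.41 ± 0.09), and the list median was 0.16, or 0.0856 with quantile normalization (camera adjusted p = 1.41e-12, and 0.825 with an estimated correlation). Of 17 genes in the list of sugar digestion and transport, the gluconeogenic Pck1 alone rose, 8 rose and 1 fell adjusted over the list alone, and the list median was 0.34, or 0.18 with quantile normalization (camera adjusted p = 7.30e-04, and 0.825 with an estimated correlation). The bile acid and sterol list held Cyp27a1, a sterol hydroxylase of bile acid synthesis, which rose 2.69-fold, as its only called member of 16 (camera adjusted p = 0.0208, and 0.825 with an estimated correlation). Lists that were called higher with medians of 0.09 to 0.13 were the unfolded protein response, where Herpud1 rose 2.36-fold, brush border, cholesterol synthesis, where Sc4mol rose by 0.95, and fat uptake, where Apoc2 rose by 0.55. Under quantile normalization their medians were 0.00858, 0.00638, 0.104 and -0.0464 in this order. Their camera adjusted p values were 0.0245, 0.0113, 0.0147 and 0.0311, and 0.825 each with an estimated correlation.

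Lists of immune and secretory cells held few called members in the cold. The B and plasma cell list had 3 rises, Igj (0.69 ± 0.09), the joining chain of secreted immunoglobulin A and M, Mzb1 (0.64 ± 0.16) and Pou2af1 (0.84 ± 0.20), out of 9 measured (camera adjusted p = 2.49e-05, and 0.825 with an estimated correlation). The list mean was 1.24 in cold replicate 2 against 0.41 and 0.39 in the other cold libraries (log2 deviation), and that of the follicle markers 1.23 against 0.06 and 0.02. Without that library Igj alone of the 3 passed. Without room temperature replicate 1 as well, a choice made after seeing the data, the list median was 0.29 and the list was not called (camera adjusted p = 0.0527). The T and intraepithelial lymphocyte markers were lower, with a median of -0.45 over 24 genes (-0.30 without room temperature replicate 1), of which Cd7 alone fell over all genes (-0.78 ± 0.16) and 12 fell adjusted over the list alone (camera adjusted p = 5.46e-10, and 0.825 with an estimated correlation). The interferon list was lower at a median of -0.15, with 26 of 42 below 0 and Irf8 (-0.64 ± 0.12) and Gbp7 (-0.73 ± 0.18) as the called members (camera adjusted p = 0.00239, and 0.825 with an estimated correlation). Tuft cell markers, of chemosensory epithelial cells, had a median of -0.46 with 0 rises and 0 falls among 17 (9 fell adjusted over the list alone, camera adjusted p = 5.11e-05, and 0.825 with an estimated correlation). Paneth cell markers and vessel markers were called higher by camera with 0 called members, at medians of 0.39 and 0.20 (adjusted p = 7.48e-04 and 0.00739, and 0.825 for both with an estimated correlation). Reg3a, a C-type lectin of the antimicrobial list, fell (-0.70 ± 0.13), Cd163 of the macrophage list rose (0.86 ± 0.21), and the anti-apoptotic list, not called, had 1 rise and 2 falls in 13, such as Bcl2l1 (0.46 ± 0.07) and Naip2 (-0.52 ± 0.08).

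The count of 305 genes depended on single libraries and on the scaling. It was 62 without cold replicate 1, 154 without room temperature replicate 2, 181 without room temperature replicate 3, 181 without cold replicate 3, and 194 without replicate 2 of the cold antibiotic group. It was 246 without cold replicate 2, and 623 without room temperature replicate 1 and cold replicate 2 together, a choice made after seeing the data. With libraries scaled to a common sum the median of all genes shifted to -0.14 on the log2 scale, and 137 genes were higher and 922 lower. Of the 20 genes with the largest rises and falls, 6 passed in each of the 12 refits without a library, Fkbp5 among them, and Pck1 passed in 2. Over these refits Fkbp5 lay between 2.47 and 3.60 on the log2 scale, Pck1 between 1.76 and 3.399, Pdk4 between 2.02 and 3.18 and Angptl4 between 1.78 and 2.83. List medians came down to 0.094 for Paneth cells and 0.0245 for the unfolded protein response without room temperature replicate 1, to 0.21 for sugar digestion without room temperature replicate 3 and to -0.00645 for interferon without cold replicate 2. They came down to 0.0535 for fat uptake, 0.0692 for brush border and 0.0753 for bile acids without cold replicate 1, and to 0.0227 for cholesterol synthesis without cold replicate 3.

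Antibiotics at room temperature lowered part of the antimicrobial and immune genes of the jejunum. Reg3b and Reg3g, antibacterial lectins secreted by the epithelium (chromosome 6, 78370657 to 78373466 and chromosome 6, 78466269 to 78468872 of GRCm38), fell 37.8-fold and 33.4-fold. Reg3g went from 3351 ± 911 to 99.8 ± 32.0 CPM (mean ± SD, n = 3), and the log2 changes were -5.24 ± 0.30 and -5.06 ± 0.23 (SE, limma adjusted p = 3.18e-07 and 8.56e-08). Ubd, a ubiquitin-like protein induced by interferon gamma, fell from 135 ± 24.7 to 0.897 ± 0.179 CPM (-6.16 ± 0.40), and Nos2 fell 28.4-fold (-4.83 ± 0.81, and -6.02 without room temperature replicate 1). Duox2 and its maturation factor Duoxa2, which make hydrogen peroxide at the epithelial surface, fell with log2 changes of -2.83 ± 0.65 and -3.06 ± 0.73. Tifa, B3galt5, the nucleic acid sensor Zbp1 and Alpk1, the kinase that senses bacterial ADP-heptose, fell with log2 changes of -2.56 to -2.99. The rises were led by Tm4sf4 (8.47-fold, 113 ± 18.3 to 958 ± 39.2 CPM). Next were the aldo-keto reductase genes Akr1c19, Akr1c13 and Akr1c14 (3.07, 2.04 and 2.01), the sulfate transporter gene Slc13a1 (2.40 ± 0.38) and Pappa2 (2.20 ± 0.13), which lay at 0.190 CPM without antibiotics, near the level of 3 reads. Pck1, Fkbp5, Hlf and Klf15 also rose, by 2.28, 2.26, 2.03 and 1.95. In all, 1744 genes passed, 808 higher and 936 lower.

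Most lymphocyte and MHC class II genes fell, and part of the interferon genes. Camera called 17 lists here, and another split of the same 6 libraries called 22. Of 24 T and intraepithelial lymphocyte markers, 22 fell and 0 rose, at a median of -1.17, among them Cd8a (-1.21 ± 0.14), Cd7 (-1.31 ± 0.16), the granzyme gene Gzma (-1.48 ± 0.17) and the chemokine gene Ccl5 (-1.46 ± 0.17), and 24 fell adjusted over the list alone (camera adjusted p = 1.18e-21, and 0.271 with an estimated correlation). Of 10 MHC class II genes, 7 fell, among them H2-Ab1 (-1.61 ± 0.21), H2-Eb1, H2-DMa and Cd74, the invariant chain, from 1821 ± 203 to 636 ± 197 CPM (camera adjusted p = 6.08e-07, and 0.271 with an estimated correlation). Of 42 interferon response genes, 17 fell and 0 rose, such as the immunoproteasome genes Psmb8 (-1.04 ± 0.09) and Psmb9 (-1.20 ± 0.13), at a list median of -0.58 (camera adjusted p = 4.60e-10, and 0.589 with an estimated correlation). The antimicrobial list had 11 falls in 22 genes, with Lypd8 (-1.33 ± 0.08) and Ido1 (-1.49 ± 0.13) beside the Reg3 genes (camera adjusted p = 6.05e-10, and 0.235 with an estimated correlation). Among B and plasma cell markers, Igj (-0.81 ± 0.09) and Mzb1 (-0.63 ± 0.16) fell, 2 of 9 (camera adjusted p = 9.63e-04, and 0.589 with an estimated correlation). Among 20 macrophage and dendritic cell markers, Lyz2 and Fcer1g fell (camera adjusted p = 0.0304, and 0.840 with an estimated correlation). Of the pro-apoptotic list, 6 of 24 fell, with Apaf1 at -0.94 ± 0.11, Casp8 at -0.44 ± 0.08 and Fas at -0.99 ± 0.21 (camera adjusted p = 0.0304, and 0.589 with an estimated correlation).

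Other lists described the epithelium and the tissue under it. Goblet cell markers had 7 falls and 0 rises in 19, such as Tff3 (-0.52 ± 0.13) and Zg16 (-0.64 ± 0.15) (camera adjusted p = 2.17e-04, and 0.631 with an estimated correlation). Collagens rose, Col1a1 by 0.80 ± 0.08, Col3a1 by 0.62 ± 0.08 and Col1a2 by 0.53 ± 0.09, in a fibroblast and extracellular matrix list with 12 rises and 0 falls in 26 (camera adjusted p = 1.27e-09, and 0.589 with an estimated correlation). Smooth muscle markers were called higher at a median of 0.25, with 17 of 19 above 0 and Actg2 (0.55 ± 0.12) as the called member (camera adjusted p = 3.55e-04, and 0.631 with an estimated correlation). Vessel markers had 5 rises and 1 fall in 21, with Kdr at 0.76 ± 0.15 (camera adjusted p = 9.63e-04, and 0.589 with an estimated correlation). Of 39 genes of xenobiotic metabolism, 13 rose and 4 fell, with Cyp2j6 up by 0.91 ± 0.10 and Cyp2c55 at -2.05 ± 0.12 (camera adjusted p = 5.09e-04, and 0.732 with an estimated correlation). Protein digestion and amino acid transport had 7 rises, such as the peptide transporter Slc15a1 (0.69 ± 0.17), and a fall of Slc36a1 (-0.68 ± 0.16), in 19 genes (camera adjusted p = 2.17e-04, and 0.631 with an estimated correlation). The unfolded protein response list had 10 rises, with the chaperone Hspa5 at 0.77 ± 0.12, and 2 falls, Chac1 (-1.41 ± 0.30) and Asns (-0.50 ± 0.12), both targets of ATF4 (camera adjusted p = 0.00179, and 0.589 with an estimated correlation). The clock list was called higher with 6 rises, such as Hlf and Usp2 (0.86 ± 0.22), and a fall of Nfil3 (-1.57 ± 0.28), in 19 genes (camera adjusted p = 0.0173, and 0.631 with an estimated correlation). Adipocyte markers had 5 falls, such as Adipoq (-2.14 ± 0.47), and 2 rises (camera adjusted p = 0.00772, and 0.631 with an estimated correlation). Their list mean varied between libraries of a group (log2 deviation). It was -0.81, -0.39 and 0.09 in replicates 1, 2 and 3 with antibiotics, and 0.49, 0.47 and 0.11 without. The amount of fat attached to the tissue was not assessed. Oxidative phosphorylation was called lower at a median of -0.09 with 0 called genes (camera adjusted p = 0.00235, and 0.918 with an estimated correlation).

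The 1744 genes became 946 without room temperature replicate 2, 998 without replicate 3 and 1148 without replicate 2 of the room temperature antibiotic group. Of the 20 genes with the largest rises and falls, 17 passed in each of the 12 refits, Duox2, Duoxa2 and Pck1 being the exceptions. Over these Duox2 lay between -3.68 and -2.16, Duoxa2 between -4.12 and -2.49, Pck1 between 1.48 and 3.12, Fkbp5 between 1.55 and 2.68 and Hlf between 1.59 and 2.62. List medians came down to -0.0369 for macrophages without room temperature replicate 1, to -0.0391 for oxidative phosphorylation and 0.36 for the clock without room temperature replicate 2, and to 0.19 for vessels without replicate 3 of the antibiotic group.

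**Figure D2:**
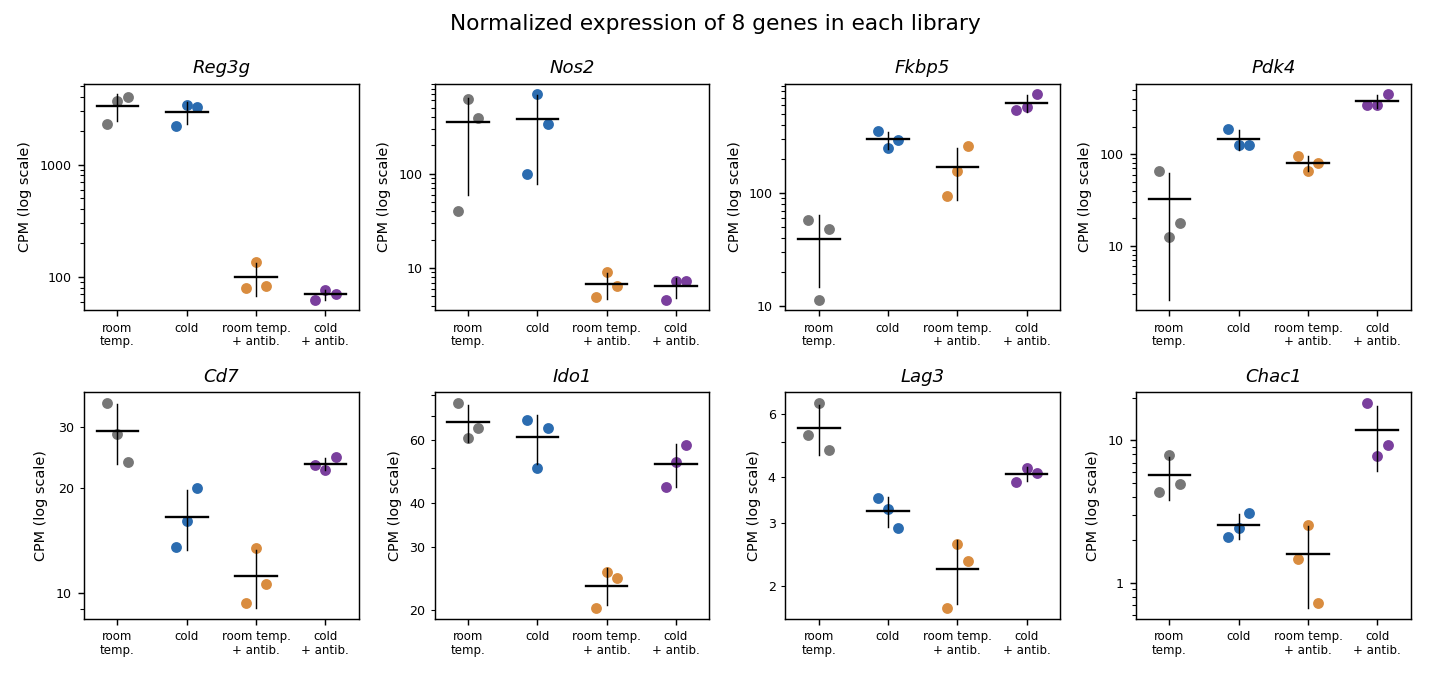
CPM of 8 genes in each library on a log axis, by group, where points are libraries of 2 pooled mice, horizontal lines are means and vertical lines SDs of 3 libraries. Reg3g lay between 2317 and 4034 CPM in the room temperature libraries and between 79.4 and 137 CPM in those with antibiotics.

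Antibiotics in the cold again lowered Reg3b and Reg3g, 47.4-fold and 41.0-fold, Reg3g from 2957 ± 651 to 70.0 ± 7.18 CPM (mean ± SD, n = 3), with log2 changes of -5.57 ± 0.30 and -5.36 ± 0.23 (SE, limma adjusted p = 1.60e-07 and 2.85e-08). Nos2, Duox2, Ubd, Duoxa2 and Ccl20 fell with log2 changes of -5.31, -4.66, -4.37, -4.13 and -3.45, followed by Casp4, Mfsd4 and the Paneth cell pentraxin Mptx2 (-2.29 ± 0.24). The rises were led by Pappa2 (2.95 ± 0.13), Akr1c19 (2.62 ± 0.31), Slc13a1 (2.62 ± 0.38) and Tm4sf4 (2.23 ± 0.16), then Akr1c13, Gk5, Akr1c14, Chac1, the interleukin 33 receptor gene Il1rl1 and Ndrg1, down to 1.67. In all, 2564 genes passed, 1348 higher and 1216 lower, and each of the 20 named here passed in each of the 12 refits without a library, over which Nos2 lay between -6.08 and -4.67, Duoxa2 between -4.60 and -3.44 and Ccl20 between -3.88 and -2.61.

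Paneth and plasma cell markers fell in most members in this comparison, where camera called 16 lists and another split of the 6 libraries 18. Of 17 Paneth cell markers, 15 fell and 1 rose, at a median of -0.99, with Mmp7, a matrix metalloproteinase, at -1.36 ± 0.19 and Itln1 at -1.03 ± 0.17 (camera adjusted p = 5.92e-08, and 0.607 with an estimated correlation). Of 9 B and plasma cell markers, 8 fell, Igj from 1385 ± 112 to 516 ± 16.9 CPM (camera adjusted p = 3.87e-06, and 0.607 with an estimated correlation). Without cold replicate 2, which was high in this list, 6 fell at a median of -0.83. The antimicrobial list had 13 falls in 22 genes, including Pigr, the transporter of immunoglobulin A across the epithelium (-1.19 ± 0.13) (camera adjusted p = 5.12e-08, and 0.359 with an estimated correlation). Goblet cell markers had 8 falls, led by Spink4 (-1.09 ± 0.12), and a rise under the symbol Clca1 (1.49 ± 0.31) (camera adjusted p = 0.00135, and 0.607 with an estimated correlation). The deposited data use older symbols and also hold Clca3, so which gene Clca1 names here is not settled. Of 22 stem cell and Wnt target genes 6 fell, such as Prom1 (-0.64 ± 0.13) and Sox9 (-0.47 ± 0.13) (camera adjusted p = 0.00319, and 0.607 with an estimated correlation). The interferon list had 9 falls, Zbp1 at -1.73 ± 0.30, and a rise of Mx1 (0.85 ± 0.15) (camera adjusted p = 0.00111, and 0.611 with an estimated correlation).

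T and intraepithelial lymphocyte markers were not called in this comparison. Their median was -0.11 (camera adjusted p = 0.566, and 0.896 with an estimated correlation), Cd7 rose (0.50 ± 0.16), and Cd8a was at 26.9 and 26.8 CPM. Of the MHC class II genes, H2-DMa (-0.54 ± 0.15) and H2-DMb1 (-0.72 ± 0.23) fell, 2 of 10 (camera adjusted p = 0.0638, and 0.607 with an estimated correlation).

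Muscle and nerve markers fell in part, and some matrix and transport genes rose. Smooth muscle markers had 6 falls in 19, with Mylk at -0.49 ± 0.10 and Acta2 at -0.40 ± 0.11 (camera adjusted p = 0.00111, and 0.607 with an estimated correlation). Enteric neuron and glia markers had 7 falls and a rise of Ednrb in 16, with Prph at -0.69 ± 0.17 (camera adjusted p = 5.90e-04, and 0.607 with an estimated correlation). Collagen genes rose again, Col1a1 by 0.70 ± 0.08, among 13 rises and 2 falls in 26 matrix genes (camera adjusted p = 5.16e-06, and 0.607 with an estimated correlation). Amino acid transport genes had 10 rises and 0 falls, with Slc6a20a at 0.75 ± 0.15 (camera adjusted p = 3.08e-04, and 0.607 with an estimated correlation). Xenobiotic metabolism had 13 rises and 4 falls, with Cyp2c55 at -2.12 ± 0.12 (camera adjusted p = 0.00111, and 0.611 with an estimated correlation). The unfolded protein response had 5 rises and 0 falls, with Ddit3 at 0.78 ± 0.10 (camera adjusted p = 0.00223, and 0.607 with an estimated correlation). The clock list had 4 rises, such as Per2 (1.06 ± 0.28) and Clock (0.63 ± 0.11), and 1 fall (camera adjusted p = 0.00489, and 0.607 with an estimated correlation). Vessel markers had 3 rises, with Flt1 at 0.76 ± 0.17 (camera adjusted p = 0.0150, and 0.607 with an estimated correlation). Oxidative phosphorylation had 10 falls, such as Cox6c (-0.32 ± 0.08), in 42 (19 adjusted over the list alone, camera adjusted p = 2.17e-07, and 0.607 with an estimated correlation), and fatty acid synthesis had 2, Scd2 (-0.50 ± 0.14) and Elovl6 (-0.37 ± 0.11) (camera adjusted p = 0.0227, and 0.607 with an estimated correlation). The count of 2564 became 1545 without cold replicate 2, 1605 and 1677 without replicates 1 and 2 of the cold antibiotic group, and 971 with the smooth muscle list as a covariate, a choice made after seeing the data. With it the median size of the 2564 changes went from 0.47 to 0.43 and their median SE from 0.11 to 0.14, and all kept their sign. List medians came down to 0.28 for amino acid transport and -0.15 for smooth muscle without cold replicate 2, to -0.20 for goblet cells without cold replicate 1, and to 0.11 for vessels and -0.17 for fatty acid synthesis without replicate 2 or 3 of the cold antibiotic group.

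The effect of antibiotics was shared between the 2 temperatures. Of 808 genes higher at room temperature, 548 were higher in the cold against 83.7 for independent lists, and of 936 lower genes 500 were lower against 87.5. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.74 and a Spearman rho of 0.63. These 2 comparisons share no library.

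Cold under antibiotics again raised Fkbp5, Pdk4, Zbtb16 and Angptl4, with G6pc at the head. G6pc, the glucose-6-phosphatase of gluconeogenesis (chromosome 11, 101367561 to 101377903 of GRCm38), rose 6.65-fold from 26.3 ± 17.7 to 163 ± 45.1 CPM (mean ± SD, n = 3), a log2 change of 2.73 ± 0.46 (SE, limma adjusted p = 0.00538). Zbtb16 (2.65 ± 0.48), Chac1, a glutathione-degrading enzyme (2.28 ± 0.30), Pdk4 (2.24 ± 0.42), Angptl4 (2.02 ± 0.40), Fkbp5 (1.99 ± 0.47), Ddit4, an inhibitor of mTORC1 (1.89 ± 0.21), Cables1, Slc16a6 and Eif4ebp3 completed the 10 largest rises. Egln3, an oxygen-sensing prolyl hydroxylase, fell from 88.5 ± 36.2 to 24.3 ± 1.91 CPM (-1.75 ± 0.22), followed by Scd2, Strip2, Fras1, the Paneth cell ribonuclease Ang4, the tuft cell genes Pou2f3, Sh2d7 and Trpm5, Lipg and Ces2b. In all, 654 genes passed, 453 higher and 201 lower. Of the 20 genes with the largest rises and falls, 13 passed in every refit without a library. With the smooth muscle list mean as a covariate, a choice made after seeing the data, 1 of the 20 passed. All 20 kept their sign in the refits and with the covariate.

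Lymphocyte and MHC class II genes rose in part here, where camera called 14 lists and another split of the 6 libraries 18. Of 24 T and intraepithelial lymphocyte markers, 8 rose and 0 fell, at a median of 0.57, with Gzma at 1.04 ± 0.17, Cd7 at 1.02 ± 0.16, Klrd1 at 0.83 ± 0.12 and Cd8a at 0.80 ± 0.14, and 16 rose adjusted over the list alone (camera adjusted p = 8.92e-11, and 0.449 with an estimated correlation). Of 10 MHC class II genes 5 rose, among them H2-Aa (1.08 ± 0.26), H2-Ab1 (0.90 ± 0.21) and Cd74 (0.91 ± 0.21) (camera adjusted p = 3.49e-04, and 0.449 with an estimated correlation). Fcer1g was the called member of the macrophage and dendritic cell list (camera adjusted p = 0.00127, and 0.685 with an estimated correlation). Fat uptake genes had 3 rises, Apoc2 (0.91 ± 0.12), Sar1b (0.33 ± 0.08) and Plin3 (0.29 ± 0.07), in 23, at a median of 0.25, or 0.0598 with quantile normalization (camera adjusted p = 2.00e-05, and 0.464 with an estimated correlation). The sterol transporter genes Abcg5 (0.37 ± 0.09) and Abcg8 (0.51 ± 0.09) rose with Cyp27a1 in the bile acid and sterol list (camera adjusted p = 0.00648, and 0.449 with an estimated correlation). In the list named sugar digestion the gluconeogenic G6pc rose, as did Dak and Mlxipl. The list median was 0.30, or 0.0937 with quantile normalization (camera adjusted p = 0.00168, and 0.686 with an estimated correlation). Brush border and oxidative phosphorylation were called higher by camera with 0 called genes, at medians of 0.16 and 0.09, and at 0.0284 and -0.0204 under quantile normalization (adjusted p = 7.87e-04 and 9.07e-04, and 0.661 and 0.807 with an estimated correlation). The clock list was called higher at a median of 0.32, with 15 of 19 above 0 and Npas2 (0.56 ± 0.12) as the called member (camera adjusted p = 0.00997, and 0.680 with an estimated correlation).

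Tuft cell and smooth muscle markers fell in part, and nerve markers were lower as a list. Of 17 tuft cell markers, 8 fell, with the master regulator Pou2f3, Trpm5 at -0.88 ± 0.18, Alox5ap at -0.83 ± 0.17 and Dclk1 at -0.79 ± 0.16 (camera adjusted p = 3.19e-08, and 0.449 with an estimated correlation). Of 19 smooth muscle markers, 7 fell, such as Acta2 (-0.52 ± 0.11) and Cnn1 (-0.46 ± 0.10), and 14 fell adjusted over the list alone (camera adjusted p = 1.03e-10, and 0.449 with an estimated correlation). Enteric neuron and glia markers had 2 falls in 16, with Prph at -0.62 ± 0.17 (camera adjusted p = 1.65e-04, and 0.449 with an estimated correlation), the stem cell list a fall of Ephb2 (-0.40 ± 0.10) (camera adjusted p = 3.48e-05, and 0.464 with an estimated correlation) and the Paneth cell list a fall of Ang4 (-1.09 ± 0.21) (camera adjusted p = 4.57e-04, and 0.686 with an estimated correlation). The smooth muscle list mean moved with the groups, from 0.19 ± 0.06 in the room temperature antibiotic libraries to -0.19 ± 0.13 in the cold antibiotic libraries (log2 deviation, mean ± SD, n = 3). With that mean as a covariate, a choice made after seeing the data, 13 genes passed, the median size of the 654 changes went from 0.51 to 0.44 and their median SE from 0.11 to 0.16 on the log2 scale, and 653 kept their sign.

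The count of 654 also became 360, 243 and 405 without replicates 1, 2 and 3 of the room temperature antibiotic group, 413, 422 and 237 without replicates 1, 2 and 3 of the cold antibiotic group, and 1115 without room temperature replicate 1 and cold replicate 2. Scaling to a common sum shifted the median of all genes to -0.12 and gave 256 higher and 884 lower genes, so here too their balance rests on the scaling. List medians came down to 0.11 for bile acids and -0.18 for stem cells without replicate 3 of the cold antibiotic group, and to 0.185 for macrophages and 0.0488 for oxidative phosphorylation without replicate 1 or 2 of the room temperature antibiotic group.

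The cold effects with and without antibiotics overlapped. Of the 209 genes higher in the cold without antibiotics, 120 were higher under antibiotics against 7.28 for independent lists, and of 96 lower genes 19 were lower against 1.48, while 2 were higher against 3.34. Across genes, Pearson r was 0.45 and Spearman rho 0.36 between the log2 changes, and the 2 comparisons share no library.

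**Figure D3:**
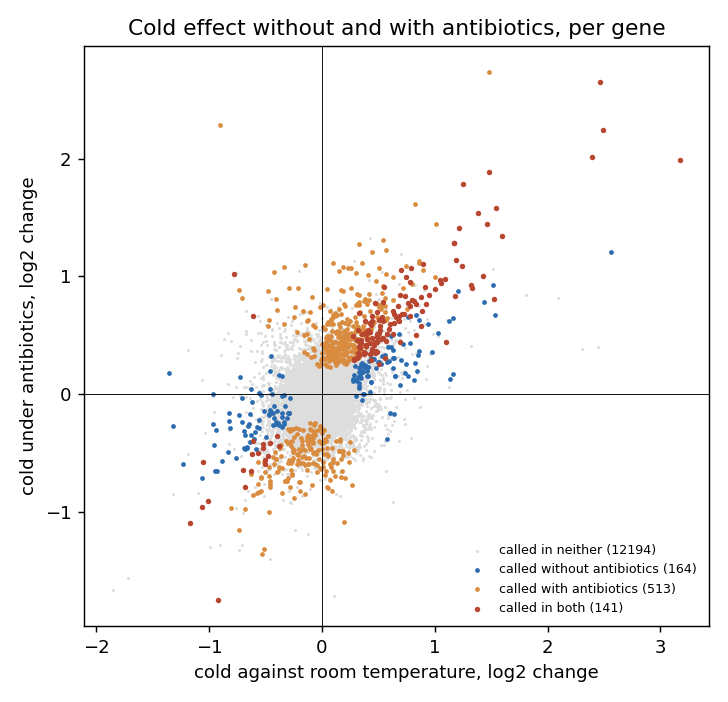
Log2 change of each tested gene in the cold without antibiotics (horizontal axis) and under antibiotics (vertical axis), on the log2(CPM + 1) scale, where points are genes and colours mark those called in both comparisons, in either or in neither. The 209 genes higher without antibiotics include 120 that were also higher under antibiotics.

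The cold effect and the antibiotic effect in the cold were set against each other, since they share the 3 cold libraries. Their log2 changes had a Pearson r of -0.06 and a Spearman rho of -0.16 across genes, where unchanged groups against the shared libraries gave a Pearson r of -0.50 in 100 simulations. The covariance was -0.0052 and the simulated one -0.0095. Of the 305 genes changed by cold, 141 had the opposite sign under antibiotics in the cold, 46.2%, where the simulation gave 90.7%. Of the 209 higher genes 41 were lower with antibiotics against 19.5 for independent lists, and 47 were higher against 21.7. Of the 96 lower genes 29 were higher with antibiotics against 9.95, and 12 were lower against 8.97. The expectation for independent lists leaves out the shared libraries, and the simulation leaves out the effects. The 3 shared cold libraries are too few to be split between the comparisons, so their part in these overlaps is not known.

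The interaction tested whether the cold effect differed with antibiotics, and 4 genes passed, each with a larger log2 change under antibiotics. Chac1 (chromosome 2, 119351229 to 119354381 of GRCm38) was at 5.73 ± 1.91 CPM at room temperature and 2.54 ± 0.501 in the cold without antibiotics, and at 1.59 ± 0.926 and 11.8 ± 5.74 with them (mean ± SD, n = 3), an interaction of 3.18 ± 0.43 (SE, limma adjusted p = 0.0252). Cd7, a surface protein of T and intraepithelial lymphocytes (chromosome 11, 121036747 to 121039418), was at 29.1 ± 5.74, 16.5 ± 3.24, 11.1 ± 2.12 and 23.4 ± 0.974 CPM in the same order. Its interaction was 1.81 ± 0.22 (limma adjusted p = 0.0213). Ido1, the tryptophan-degrading dioxygenase (chromosome 8, 24584136 to 24597009), had an interaction of 1.25 ± 0.19 and Lag3, a lymphocyte checkpoint receptor (chromosome 6, 124904361 to 124911705), one of 1.27 ± 0.19 (limma adjusted p = 0.0449 for both). Gzma, next by p, did not pass (1.46 ± 0.24, limma adjusted p = 0.0861). Without a correction 1222 genes had a p under 0.05.

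By list, the T and intraepithelial lymphocyte markers had a median interaction of 1.03, with Cd7 as the called member of 24 and 20 higher adjusted over the list alone (camera adjusted p = 3.73e-29, and 0.271 with an estimated correlation). The MHC class II genes had a median of 0.97 with 0 called genes, and 7 higher adjusted over the list alone (camera adjusted p = 7.06e-07, and 0.271 with an estimated correlation). Paneth cell markers were lower at -0.88, or -0.56 without room temperature replicate 1 (camera adjusted p = 1.50e-10, and 0.513 with an estimated correlation) and smooth muscle markers at -0.47 (camera adjusted p = 9.46e-16, and 0.271 with an estimated correlation). Camera called 13 of 39 lists here, and 61 of 100 assignments of the residuals to the libraries, the real one included, called as many.

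The 4 interaction genes depended on single libraries. The count was 0 without room temperature replicate 2, cold replicate 1, replicate 1 or 3 of the room temperature antibiotic group or replicate 3 of the cold antibiotic group, 1 without cold replicate 3, 2 without room temperature replicate 1 or cold replicate 2, and 11 without replicate 2 of the room temperature antibiotic group. It was 2 with edgeR and 87 with DESeq2 on whole reads, and 0 with the smooth muscle list as a covariate, where Cd7 went to 1.32 ± 0.29 and Chac1 to 3.29 ± 0.66.

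**Figure D4:**
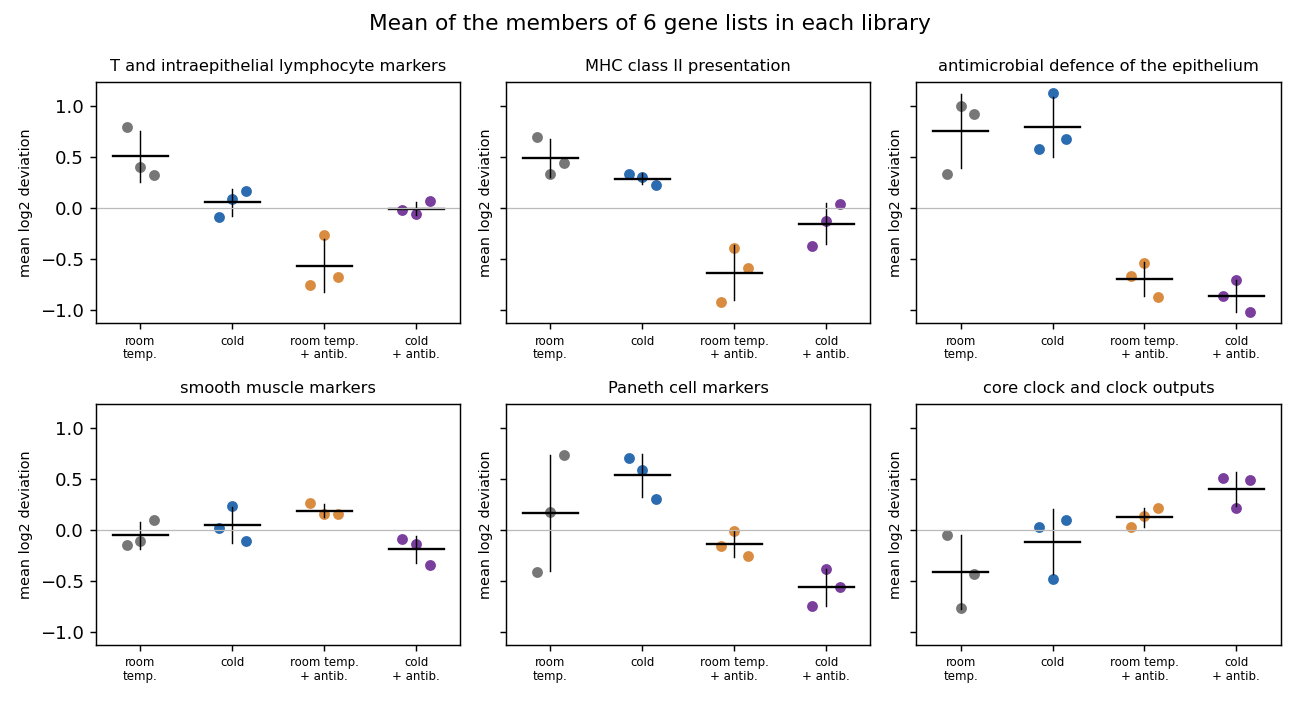
Mean of the members of 6 gene lists in each library, as log2 deviation from the mean of all 12 libraries, where points are libraries of 2 pooled mice, horizontal lines are means and vertical lines SDs of 3 libraries. The smooth muscle mean was 0.19 in the room temperature antibiotic group and -0.19 in the cold antibiotic group.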

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

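The tests of the epithelium, of follicle tissue and of 1 source for Rn45s and Lars2 reads, the draws for single lists and the counts of other splits were chosen only after the result was seen. The results below are differences in the cold effect between mice with and without antibiotics, each from the test of the interaction.

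The genes were Cd7 with an interaction of 1.81, Chac1 with 3.18, Ido1 with 1.25 and Lag3 with 1.27 on the log2 scale (limma adjusted p = 0.0213, 0.0252, 0.0449 and 0.0449). Of 100 assignments of the residuals to the 12 libraries, the real one included, 2 called as many as 4 genes and the highest other called 13, so the share is under 0.05. The residuals still hold the interaction itself, which adds to the spread of the other draws and can lower their counts. Each gene kept its sign in the 12 refits without a library, and Cd7 passed in 7 of them, Chac1 in 5, Ido1 in 2 and Lag3 in 2.

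The lists, by median interaction, were T and intraepithelial lymphocyte markers at 1.03, MHC class II presentation at 0.97, macrophage and dendritic cell markers at 0.28, interferon response at 0.18, fat uptake at 0.11, oxidative phosphorylation at -0.0738. Lower were tuft cell markers at -0.25, stem cell and Wnt target genes at -0.28, cholesterol synthesis at -0.28, enteric neuron and glia markers at -0.46, smooth muscle markers at -0.47, B and plasma cell markers at -0.49 and Paneth cell markers at -0.88. None of these 13 passed with an estimated correlation, where the lowest camera adjusted p was 0.271, and 61 of the 100 assignments called at least 13 lists (highest other 21), so the number of lists does not set the real grouping apart. Without 1 library the interferon median changed sign (-0.0346), and those nearest 0 were 0.0424 for fat uptake, -0.0168 for oxidative phosphorylation, 0.121 for macrophages, -0.118 for tuft cells, -0.173 for stem cells, -0.145 for cholesterol synthesis, -0.324 for B and plasma cells and -0.563 for Paneth cells. Taken list by list, a median as far from 0 came up in 2 of 100 assignments for the lymphocyte, MHC class II and smooth muscle lists, 1 for neuron and glia, 3 for Paneth, 4 for stem cell, 10 for cholesterol synthesis and for B and plasma cells, 14 for macrophage, 22 for tuft, 25 for fat uptake, 46 for oxidative phosphorylation and 54 for interferon, without correction for the 42 lists drawn.

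The lymphocyte markers fell with antibiotics at room temperature (median -1.17) and not in the cold. A lower share of epithelium would lower brush border genes as well, and their median was -0.0157. Matrix, vessel and smooth muscle lists had medians of 0.43, 0.30 and 0.25 there, and the neuron and glia list -0.0774. Values scaled to the whole tissue give shares, so a shift between tissue layers is not excluded. A single deviating library would be lost when left out, but the lowest median interaction in the 12 refits was 0.892, and it was 0.714 with the smooth muscle list, itself lower in the interaction, as a covariate, where 0 genes passed. Follicle tissue would carry its own markers along, and these had a median interaction of -0.218 (SD 0.44 over 8 genes), and of 0.0355 (SD 0.371) without cold replicate 2, which was rich in them. A change in the number or state of lymphocytes with cold and antibiotics may therefore remain, as a hypothesis found and tested on the same 12 libraries, but cell numbers were not measured, and how much goes with the share of muscle is not known.

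The 9 clock output genes had medians of 1.31 with antibiotics at room temperature, where 4 passed, and 1.06 in the cold, where 2 passed, and these medians went down to 0.763 and 0.579 without replicate 2 of the untreated group. In the cold, the clock list stayed called by camera without the library rich in ribosomal RNA (adjusted p = 0.0211), while with all libraries and an estimated correlation its p was 0.607. A different time of day at collection would lower genes of the opposite phase, Arntl, Npas2, Clock and Nfil3, whose mean of medians was -0.227. That value passed the bound of -0.2 written beforehand, but the members went both ways, Nfil3 fell at room temperature while Clock rose in the cold, and after seeing them the outcome was set to undecided. By library, replicate 2 of room temperature and of cold lay at -1.52 and -1.08 in the output genes (mean log2 deviation). In the opposite genes they lay at 0.507 and 0.444, as a shifted clock phase in these libraries would give. The other untreated libraries lay at -0.825 to 0.0942 and at -0.185 to 0.0759. The cold antibiotic libraries lay at 0.389 to 0.866 and at -0.0372 to 0.157. Collection time may or may not differ between the groups and cannot be told apart from them, as the times are not given in the sources used here.

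Cold replicate 2 held 10.1% Rn45s reads. Lars2 followed Rn45s in 1 ratio in the 3 libraries with most Rn45s (highest over lowest 1.23), which is consistent with 1 ribosomal RNA source for both. Incomplete selection of poly(A) RNA could also raise histone mRNAs without poly(A) tails. On the scale of CPM + 1, 4 of them had a median log2 ratio of 0.489 (SE 0.11) in that library. Rpph1, a ribozyme RNA without a tail, was at 81.7 CPM against 0.828 and 1.09 in the other cold libraries. It was at 7.32 CPM in replicate 3 of the cold antibiotic group, where Rn45s took 0.812% of reads. In replicate 3 of the room temperature antibiotic group, with 0.423%, it was at 0.602 CPM. The histone value lies under the bound of 0.5 that was to count against this source, by less than its SE. Some of these genes lay near 1 CPM, such as Hist2h3c2 at 1.83 against 0.828 and 1.16 CPM. There the scale of CPM + 1 understates the ratio, so the histone value cannot count against this source. These 4 genes were picked when the test was coded, and Rpph1 goes with this source but is 1 gene. The source therefore cannot be told apart from others. No biological explanation was tested.

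For the counts of genes, splits of 6 libraries are too few for a share under 0.05, as there are 10. The real count and the highest other were 305 and 70 for cold against room temperature, 1744 and 0 for antibiotics at room temperature, 2564 and 0 for antibiotics in the cold, and 654 and 0 for cold under antibiotics, with 1 of 10 splits as large in each. Every other split mixes both conditions in its groups, so a true difference widens its spread and lowers its count. Low counts in the other splits are therefore no support for the real ones. For the number of lists, 7, 4, 4 and 5 of the 10 splits called as many, and the highest other splits called 25, 22, 18 and 18 where the real ones called 13, 17, 16 and 14. Camera with the preset correlation thus called as many lists in groupings that mix the conditions.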

How the results depend on the processing

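The smooth muscle covariate and the removal of room temperature replicate 1 with cold replicate 2 were chosen only after the data were seen. Where no reason is given, the cause was not tested. A common sum lowers the cold libraries against the room temperature ones, as their deposited sums were all higher. In cold replicate 2, 109526 of 1.08e+06 CPM were Rn45s, so ribosomal RNA was part of its higher sum. The other cold libraries, with or without antibiotics, held 762 to 8819.5 CPM of it. Counts of genes outside 1.5 times the reported ones, or below it, were as follows. For cold against room temperature (305), 1059 with a common sum, 141 without a variance trend, 495 with array weights, 42 in its 6 libraries alone, 584 with DESeq2, 62 to 352 without 1 library and 623 without both. The 6 libraries alone leave fewer degrees of freedom and their own estimate of the spread, which were not separated. For antibiotics at room temperature (1744), 946 to 2140, and 2455 without both. For antibiotics in the cold (2564), 1545 to 2887, and 971 with the covariate. For cold under antibiotics (654), 1140 with a common sum, 1309 with array weights, 1147 in its 6 libraries alone, 237 to 847 without 1 library, 1115 without both, and 13 with the covariate, which follows the groups and raised the median SE from 0.11 to 0.16. For the interaction (4), 2 with a pseudocount of 0.25, 1 at a mean of 10 CPM, 0 without a trend, 2 with edgeR, 87 with DESeq2, 0 with the covariate and 0 to 11 without 1 library; 1222 genes had an unadjusted p under 0.05. Leaving out a library leaves 2 in its group, which are taken to vary like the others.

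Camera lists with an estimated correlation numbered 0, 0, 0, 0 and 0 in the 5 comparisons, and with fry, which asks if a list moves at all, 0, 7, 4, 8 and 0. List directions that reversed had these camera adjusted p values: with quantile normalization 0.864 for fat uptake in cold against room temperature and 0.713 for oxidative phosphorylation in cold under antibiotics. With the covariate they were, in cold under antibiotics 0.515 for sugar digestion, 0.925 for Paneth cells, 0.899 for the clock and 0.569 for oxidative phosphorylation, and in the interaction 0.613 for fat uptake and 0.613 for B and plasma cells. Across genes, r of the cold effects went to 0.416 with a pseudocount of 0.25 and 0.575 at a mean of 10 CPM (0.383 to 0.495 without 1 library), r of the antibiotic effects to 0.717 and 0.824 (0.693 to 0.771), and r of cold against antibiotics in the cold to 0.0221 at a mean of 10 CPM (-0.179 to 0.101). At 14152288 reads, 3 reads are 0.229 CPM, below which a level cannot be told from 0.

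With the replicate block the counts were 368, 1882, 2700, 768 and 0. The replicate numbers do not pair the libraries by any label, and 18 same-numbered pairs of residuals correlated at -0.11 to 0.249 (median 0.0476), with 9 of 12 libraries matching best with their own number.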

Other observations

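The lists of glucocorticoid-induced, FoxO and fasting, and ATF4 target genes were added only after the results were seen, without the genes that prompted them, and tested after their predictions were written. Their camera p values were adjusted over these added lists alone, a smaller family than that of the first lists. Adjusted p values of the added and the first lists, also those with an estimated correlation, therefore cannot be compared directly. The added lists kept 3, 1 and 5 genes of the first lists, such as Asns and Ddit3, whose values had been seen. Without those the larger camera adjusted p in the cold was 4.73e-07 for glucocorticoid-induced genes (0.0170 and 0.0155 with an estimated correlation) and 4.34e-05 for FoxO and fasting genes (0.0708 and 0.0220). For ATF4 targets it was 0.00140 in the interaction (camera, and 0.0489 with an estimated correlation).

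Glucocorticoid-induced genes may underlie part of the cold response, as Fkbp5 and Zbtb16 rose at both antibiotic states. The 18 listed genes without those had 6 rises and 0 falls in the cold, namely Cdkn1a, Dusp1, Klf9, Mt1, Mt2 and Sult1a1. In the cold under antibiotics they had 5 rises and 0 falls, namely Bcl6, Cdkn1a, Cebpd, Sult1a1 and Tsc22d3. Only Cdkn1a and Sult1a1 passed in both. The larger of both camera adjusted p values was 2.87e-08 (0.0237 and 0.0224 with an estimated correlation). Some of them also rose outside cold, as antibiotics at room temperature gave 8 rises, Mt1 and Mt2 among them, and 2 falls. The median there was 0.30 (camera adjusted p = 0.0296, and 0.354 with an estimated correlation). Without the 3 genes of the first lists there were 6 rises and 2 falls, and the list was not called there (camera adjusted p = 0.115, and 0.413 with an estimated correlation). FoxO and fasting genes were higher as a list in both, at medians of 0.23 and 0.34 with 1 and 6 rises in 19, and the larger camera adjusted p was 0.000164 (0.0773 and 0.0247 with an estimated correlation). All mice were fasted for 5 hours, and neither hormone levels nor food intake were analysed here. Collection times are not given in the sources used here either. Stress, fasting, a greater demand for fuel in the cold and a different time of day at collection therefore cannot be separated.

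Chac1 may be part of an amino acid response through ATF4. The 21 other tested targets had 7 rises in the cold under antibiotics, among them Asns, Psat1 and Aars, and a median interaction of 0.31 with 0 called genes (camera adjusted p = 4.62e-05, and 0.0646 with an estimated correlation). Part of that difference lies outside cold with antibiotics. With antibiotics at room temperature 2 rose and 5 fell at a median of -0.20 (camera adjusted p = 0.0255, and 0.354 with an estimated correlation), and in the cold without them 0 were called at a median of 0.16 (camera adjusted p = 0.0144, and 0.146 with an estimated correlation). A median interaction as far from 0 came up in 1 of 100 assignments of the residuals to the libraries. Since camera with the preset correlation also called many lists in other groupings, its small p values carry less weight than their size.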
